A study of Oryctolagus cuniculus with 4 samples.

How the data were processed

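Total RNA of rabbit ligamentum flavum was labelled with Cy3 and hybridised to single-colour Agilent rabbit arrays, 1 array for each of 4 groups, per the labels. Whether RNA of several animals was pooled, whether L2/3 and L4/5 were pooled within a sample, and whether controls came from unoperated animals are not given in the sources used here. Spots were read with Agilent Feature Extraction 12.0.3, per the submitters' processing notes. The deposited scanner values are spot intensities on a linear scale, and the processed signal used here is, per the file headers, background-subtracted and spatially detrended within each array, with no scaling between arrays. The files also hold Feature Extraction's marks for each spot (well above background, saturated, non-uniform), per the file headers. All 4 arrays lie on 1 slide, so slide is no batch between groups.

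The authors' deposited value table holds linear intensities that equal the processed signal times 1 factor per array. Its scale and direction are thus known, while how the factors were chosen is not. Its medians are 515.5 for the ISC level, 442.3 for the control of L3/4, 498.4 for the fused levels and 504.0 for the control of L2/3 and L4/5. It was used only as an alternative.

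For the values reported, log2 of the processed signal was taken and each array's 75th percentile over non-control probes subtracted. That percentile was a signal of 93.8 for the ISC level, 53.4 for the control of L3/4, 85.4 for the fused levels and 72.8 for the control of L2/3 and L4/5. Control spots and spots marked as non-uniform or population outliers (3 to 7 per array) were left out, no spot was saturated, and spots of 1 probe were averaged. The median SD of log2 signal over replicate spots of a probe lay between 0.097 and 0.137 on the 4 arrays. This is a technical spread within arrays and says nothing of animals. The number of arrays limits the precision.

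The files give accessions but no gene symbols. RefSeq accessions without versions were looked up in a RefSeq table of the assembly mOryCun1.1, used for names alone, since the array design refers to another build, and no coordinates are given. This named 3792 of 43603 probes (8.70%) and 1489 genes. A further 24690 probes carry Ensembl transcript identifiers and 6115 only a probe name, and these are unnamed here. Of 18 genes fixed to be reported where measured, 6 could be named (COL1A2, COL2A1, TNMD, ACTA2, TGFB2 and MMP2). The genes of elastic fibres, ELN and FBN1 among them, are therefore not reported here. A feature is a named gene or, without a name, an accession or probe name, which gave 22901 features. A gene with several probes is represented by the probe with the highest mean signal over the 4 arrays, and the range over its probes is given where it matters. For transcripts with 2 probes, the ratios of the probes correlated across transcripts at r = 0.771 for the ISC level, 0.861 for the fused levels and 0.775 for the controls. Where the first of 2 probes was at 2-fold, the second had the same sign in 91.3%, 97.0% and 92.5% of transcripts, in that order. It was itself at 2-fold in the same direction in 61.3%, 68.5% and 60.9% only, so many calls at 2-fold depend on the probe. Among called genes with several measured probes, 4 of 78 for the ISC level and 5 of 86 for the fused levels had a probe of the opposite sign.

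A feature was measured in a comparison when well above background on both arrays. Differences of at least 2-fold were counted with no test. Where a gene was well above background on 1 array only, its bound sets its signal there against the higher of its own signal and the lowest signal well above background on the other array. The 30 gene lists, 830 symbols in all, were fixed before the data were examined, as were the size of 2-fold, the alternatives and the rule for named genes. Of the symbols, 145 could be named on the array, and 9 lists had fewer than 3 named genes. The median ratio of a list with at least 3 measured members was placed among 10000 random lists of the same size, drawn from 20 bins of mean signal. A list below percentile 2.5 or above 97.5 is said to stand apart, as a description of these arrays and not as a test of conditions. Of 19 lists scored for the ISC level 4 stood apart, of 18 for the fused levels 6, and of 18 for the controls 3.

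The genes named are the 10 highest and 10 lowest with a symbol in each comparison, up to 2 highest and 2 lowest members of each list, the 18 fixed genes, and the 3 largest bounds, with some left out for length and some not reported here. Genes outside this rule are said to have been named after their values were seen.

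Alternatives were quantile normalization, cyclic loess, centring on the median of probes well above background on all 4 arrays, other filters on dim probes, the mean over a gene's probes, the authors' scaled values, the mean of the controls, other fold sizes and the mean of a list. Normexp was planned on mean spot signals, which the files used here do not hold. It was run on median spot signals and local background with an offset of 50, as an alternative chosen after seeing the data, as was the use of the other control array. Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The steps were tested on simulated data with a noise SD of 0.115, where 200 of 200 probes changed 3-fold were recovered and 0 unchanged ones called in each comparison, and 5.5%, 6.0% and 4.5% of 200 lists of unchanged genes stood apart for the ISC level, the fused levels and the controls. The simulation holds spot noise only, with no spread between animals. Its noise is far below the SD of 0.831 of the ratio of the controls over features, so the recovery tests the steps and not these data. The unchanged lists were random draws, like the lists they were placed among, so their rate follows from the cutoffs. It does not show how often lists of genes that vary together stand apart.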

Results

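Gene expression was measured in the ligamentum flavum, the elastic ligament that joins neighbouring vertebral arches, of male rabbits aged 34 weeks. All 4 samples are labelled as 16 weeks after surgery, but whether the controls were operated on is not given. Per the labels, muscle over L3/4 was resected and the levels above and below it, L2/3 and L4/5, were fused posterolaterally with instrumentation, so that mechanical stress was concentrated at the free level between them. The 4 groups were the intervertebral stress concentration (ISC) level at L3/4, the control of L3/4, the fused levels L2/3 and L4/5, and the control of those levels. Each group was measured on 1 single-colour Agilent array, all 4 on 1 slide, and each array held 43603 distinct probes. Between 59.6% of probes in the control of L3/4 and 67.9% in the ISC level were well above background. With 1 array per group there are no replicates, so no ratio below has an error, a p-value or a check against the spread between animals, and the number of arrays limits the precision. Ratios are differences of log2 signal scaled to each array's 75th percentile. A difference of at least 2-fold is used as a fixed size, not as a test. For many genes and lists the ratio to the other control array is given as well, an alternative chosen after the data were seen.

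The comparison of the ISC level with the control of L3/4 asks which transcripts differ in a ligament under concentrated mechanical stress. The muscle over the stressed level was also resected, and whether controls were operated on is not given. Stress and local surgery therefore cannot be told apart here. Matrix and remodelling genes were among those with higher signal at the ISC level. COL8A1, which encodes a chain of the short-chain collagen VIII, was higher by 1.30 on the log2 scale, and by 1.20 when set against the other control. COL1A2, a chain of type I collagen, was higher by 0.89, under 2-fold, and by 0.37 to the other control, and its 11 probes ranged from 0.73 to 1.49. BGN, the small proteoglycan biglycan, was higher by 1.27, with 2 probes at 0.47 and 1.27, and by 0.15 to the other control. Of 9 measured matrix proteases and inhibitors, 3 were at least 2-fold higher and 0 at least 2-fold lower: the collagenase MMP13 by 2.25, the cysteine protease CTSK by 1.27 and the metalloprotease inhibitor TIMP1, named after its value was seen, by 1.05. None of the 3 was 2-fold apart from the other control, with MMP13 at 0.45, CTSK at 0.37 and TIMP1 at 0.03. The median of this list was 0.56, at percentile 99.1 of random lists matched on signal, while against the other control it was 0.37, at percentile 96.3. MMP2, a gelatinase, was at 0.48. Among the genes of cartilage and tendon identity, COL2A1 was at −0.08, TNMD at −0.09, LUM at −0.57 and OGN at −0.60.

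Growth factor genes went in both directions at the ISC level. TGFB2 was higher by 1.27 and FGF2 by 1.15, whereas FGF7, a fibroblast-derived epithelial mitogen, was lower at −2.37, IGF1 at −2.43 and BMP4 at −1.31. TGFB2 was at 0.22, FGF2 at 0.66, FGF7 at −0.28 and BMP4 at −0.40 against the other control, all under 2-fold. The receptor gene FGFR2 was higher by 1.11 than in the control of L3/4 and lower, at −1.50, than in the other control. The TGF-beta and BMP list had a median of 0.21 and the FGF list a median of 0.48, at percentiles 75.2 and 83.6 of the random lists. With features well above background on at least 1 array the FGF median was 1.11 and the list stood apart, and against the other control the TGF-beta and BMP median was −0.14.

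Contractile genes of smooth muscle and myofibroblasts were lower at the ISC level, with 3 of 6 measured members at least 2-fold lower and a median of −0.90 at percentile 0.48. MYH11, the smooth muscle myosin heavy chain, was at −2.19, TPM2 at −1.16 and ACTA2, smooth muscle actin, at −1.05. Against the other control the list was also lower, with a median of −0.91 at percentile 0.06, but that control held high signal of skeletal muscle genes, and 3 of the 6 members (DES, TPM1 and TPM2) are expressed in skeletal muscle as well. MYH11 was then at −0.92, ACTA2 at −0.42 and CALD1, which was at −0.69 to the matched control, at 0.28. Both measured endothelial genes were lower at the ISC level beside this list, KDR at −1.32 and SOX17 at −2.58, as were the haemoglobin genes HBA at −0.89 and HBB2 at −0.80, under 2-fold. To the other control SOX17 was at −1.09, HBA at 0.70 and HBB2 at 0.65, and KDR was not well above background there. Of the 4 mitochondrial respiration genes measured, ATP5PO at −1.15 and SDHD at −1.07 were at least 2-fold lower, with a list median of −0.81 at percentile 1.44. This median was −0.22 against the other control and −0.64 with the probes of a gene averaged, and did not stand apart in either, and it was −0.41 with normexp. The Schwann and neural list of 3 genes had a median of −1.07 at percentile 0.69, with S100B at −1.07, and its median was 0.16 against the other control. Skeletal muscle genes did not stand apart at the ISC level, with a median of −0.26 at percentile 33.3, but had a median of −4.71 against the other control and of −2.56 against the mean of the controls, both at percentile 0.00.

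Among the genes with the highest ratios at the ISC level were SAA3, an acute-phase serum amyloid A, at 3.55, the lipase gene LPL at 2.43, the gap junction gene GJA1 (connexin 43) at 2.25, the lipoprotein receptor gene VLDLR at 2.20 and PAPSS2, which makes the sulphate donor for proteoglycans, at 2.06. BRK1 at 2.70, E2F6 at 2.58, MOSPD2 at 2.43, CHD2 at 2.42 and SPTLC1 at 2.16 had ratios of the same size. CCL2, a monocyte chemoattractant, was higher by 1.54. Of 11 measured inflammatory cytokines and chemokines 3 were at least 2-fold higher and 2 at least 2-fold lower, LIF at −1.77 and IL1A at −1.49. The median of that list was 0.11 at percentile 87.3, which was not apart. To the other control LIF was at −1.015 and IL1A at 0.28, IL1A not being well above background there. Among the genes with the lowest ratios were GTF2A1L at −3.39, CASQ2, a cardiac and slow muscle calsequestrin, at −3.11, ITIH6 at −2.74, PRKCB at −2.58, the endothelial transcription factor gene SOX17 at −2.58 and SLN, sarcolipin, at −2.34. Many of these genes were under 2-fold apart from the other control, with SAA3 at 0.03, LPL at 0.43, GJA1 at 0.78, PAPSS2 at 0.59, BRK1 at 0.38, CHD2 at 0.39 and CCL2 at 0.38. VLDLR at −1.27, PRKCB at 0.49 and IGF1 at 0.67 had the opposite sign there, IGF1 not being well above background in that control. E2F6 at 1.81, MOSPD2 at 2.23, SPTLC1 at 1.61, GTF2A1L at −2.17, CASQ2 at −2.62, ITIH6 at −1.34, SLN at −5.03 and SOX17 at −1.09 were at least 2-fold apart from both controls. Among genes well above background on 1 of the arrays only, CYP4A7 was at least 17.9-fold lower, DAO at least 13.0-fold lower and SLC5A2 at least 9.71-fold higher at the ISC level. None of these differences held against the other control, where the log2 ratios were 1.29 for CYP4A7, −0.60 for DAO and 0.53 for SLC5A2. CYP4A7 and DAO were not well above background at the ISC level.

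In all, 13731 features (genes or transcripts) were well above background on both arrays, of which 1247 were at least 2-fold higher and 1440 at least 2-fold lower at the ISC level. Of the features called 2-fold higher and measured on the other control too, 159 of 1229 were also 2-fold higher than that control, and of those called lower, 187 of 1258. The share of calls that were higher was 46.4%, and it was 58.9% with the authors' scaling, which moves the median of all features by 0.13, and 66.3% with normexp background correction.

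**Figure D1:**
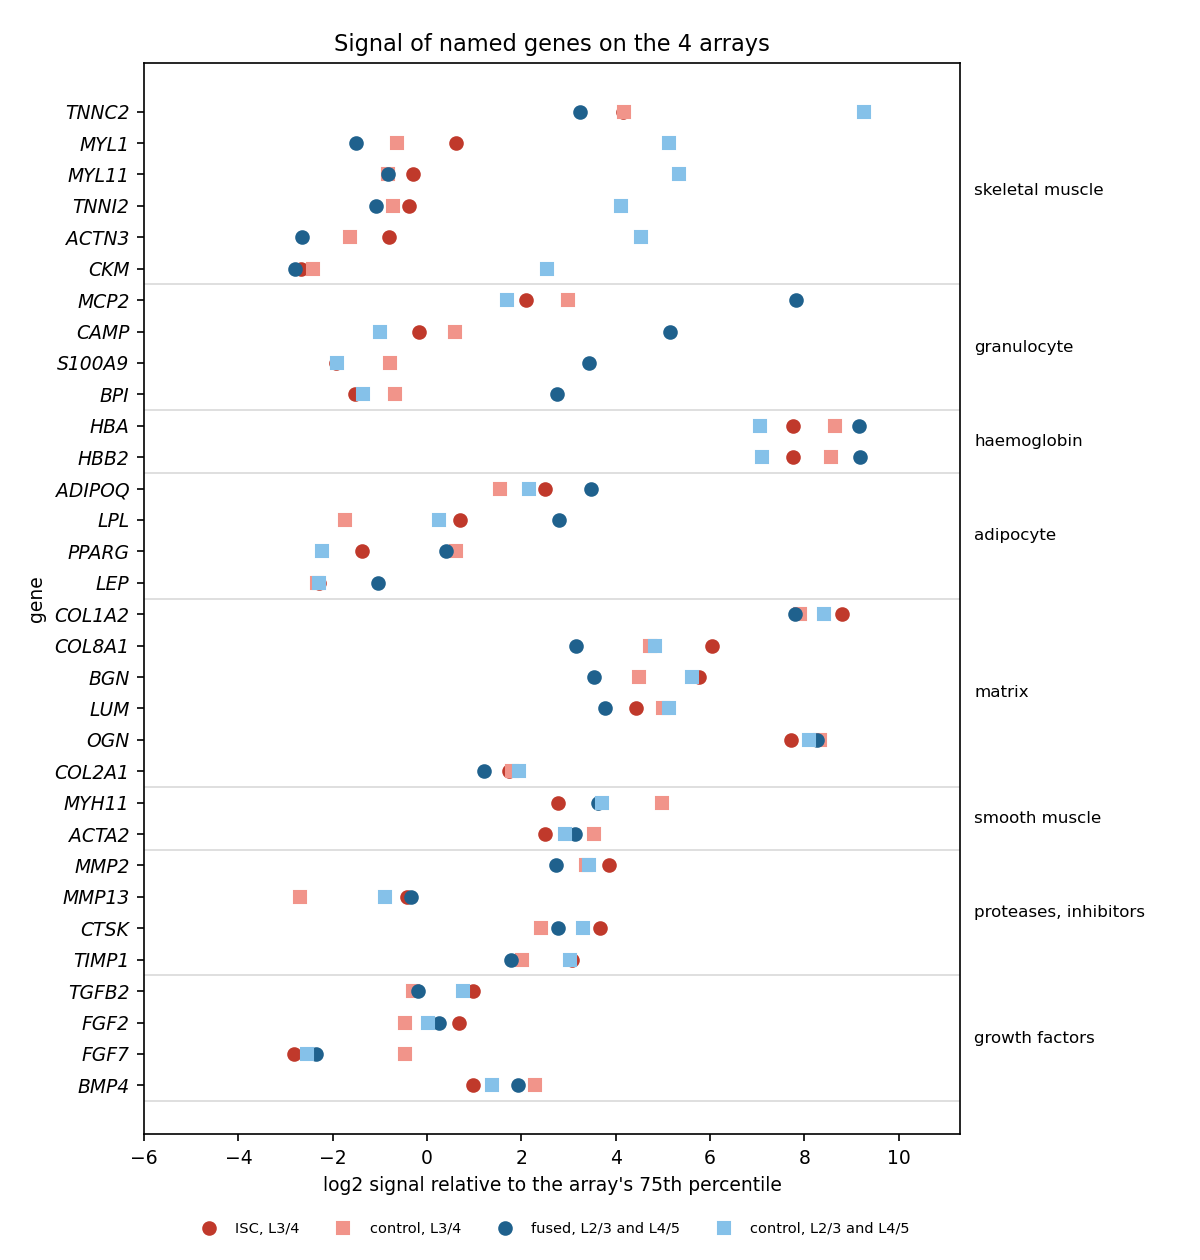
Signal of named genes on the 4 arrays, 1 symbol per array (circles, ISC and fused levels; squares, controls), on the log2 scale relative to each array's 75th percentile. Skeletal muscle genes are highest in the control of L2/3 and L4/5 and granulocyte genes in the fused levels, with median log2 signals there of 3.46 over 12 muscle genes and 4.29 over 4 granulocyte genes.

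The comparison of the fused levels with the control of L2/3 and L4/5 asks which transcripts differ in a ligament relieved of movement. The fused levels also had the fusion surgery and its instrumentation, so relief of movement and surgery cannot be told apart here. Genes of granulocytes had the highest ratios at the fused levels. MCP2, a defensin, was higher by 6.15 on the log2 scale, CAMP, the precursor of the cathelicidin antimicrobial peptide, by 6.14, S100A9, a calprotectin subunit, by 5.34 and BPI, a bactericidal protein of neutrophil granules, by 4.12. The 5 probes of CAMP ranged from 6.13 to 6.33. SRGN, the proteoglycan of secretory granules, was higher by 4.87. All 3 measured members of the neutrophil and marrow list were at least 2-fold higher, with a median of 5.34 at percentile 99.95. Against the other control the median was 4.22, and MCP2 was higher by 4.84, CAMP by 4.56, S100A9 by 4.22, SRGN by 3.64 and BPI by 3.44. Haemoglobin genes were higher as well, HBA by 2.10 and HBB2 by 2.06, and by 0.52 and 0.61 against the other control.

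Adipocyte genes were also higher at the fused levels, with 4 of 5 measured members at least 2-fold higher and a median of 1.32 at percentile 99.85. PPARG was higher by 2.63, LPL by 2.55, ADIPOQ, the adiponectin gene, named after its value was seen, by 1.32, and LEP, the leptin gene, by 1.24. Against the other control LPL was higher by 4.55, ADIPOQ by 1.93 and LEP by 1.30, while PPARG was at −0.22. Of 9 measured inflammatory cytokines and chemokines 4 were at least 2-fold higher and 1 at least 2-fold lower. IL1RN, the interleukin-1 receptor antagonist, was higher by 2.79 and PTGS2, cyclooxygenase-2, by 2.44, with PTGS2 probes from 0.14 to 2.44. IL1B was at least 21.8-fold higher, being not well above background in the control. The list had a median of 0.04 at percentile 75.3, and of 1.63 against the other control, where it stood apart.

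Skeletal muscle genes had the lowest ratios at the fused levels. Of 16 measured members, 15 were at least 2-fold lower, and the median was −5.28 at percentile 0.00. The fast-fibre actinin gene ACTN3 was at −7.18, the muscle glycogen phosphorylase gene PYGM at −6.74, the myosin light chain genes MYL1 and MYL11 at −6.65 and −6.18, the enolase gene ENO3 at −6.16, the troponin genes TNNC2 and TNNI2 at −6.02 and −5.20, PPP1R3A at −5.73, MYOZ1 at −5.56 and the creatine kinase gene CKM at −5.36. These genes were high in the control of L2/3 and L4/5. The control of L3/4 had lower signal than that control, with a median ratio of −4.85 over the same list. Against the control of L3/4, the fused levels had a list median of −0.97, with ACTN3 at −1.01, MYL1 at −0.87, MYL11 at −0.01, TNNC2 at −0.93 and CKM at −0.40. PYGM and MYOZ1 were not well above background in the control of L3/4. CASQ1 was at least 86.8-fold lower and ANKRD1 at least 42.9-fold lower at the fused levels than in the control of the same levels. To the control of L3/4 the log2 ratios were −3.17 for CASQ1 and −0.28 for ANKRD1. Neither gene was well above background at the fused levels, and ANKRD1 was not in the control of L3/4 either. Glycolysis genes lay lower with the muscle genes: 6 of 9 were at least 2-fold lower, with a median of −1.53 at percentile 0.00, ALDOA at −3.30, LDHA at −2.45 and GAPDH at −2.31. Against the control of L3/4 the glycolysis median was 0.00, and the control of L3/4 was below the other control by a median of −1.25.

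Genes of matrix proteins ranged from lower to little different at the fused levels. BGN was at −2.07, COL8A1 at −1.68, LUM, the small proteoglycan lumican, at −1.36, CNMD, chondromodulin, at −1.01, and under 2-fold COL2A1 at −0.74, MMP2 at −0.70 and COL1A2 at −0.62, while OGN was at 0.18 and DCN, decorin, at 0.07. TNMD, tenomodulin, a marker of tendon and ligament cells, was well above background in the control of L2/3 and L4/5 and not at the fused levels, which were at least 3.33-fold lower. Against the control of L3/4, COL8A1 was at −1.58, LUM at −1.22, BGN at −0.95, CNMD at −0.87, MMP2 at −0.64 and COL1A2 at −0.10. The tendon and ligament list had a median of −0.65 at percentile 5.05, which was not apart, over members that leave out TNMD as not well above background at the fused levels. Counting features well above background on at least 1 array, which takes in TNMD, its median was −1.36 at percentile 0.46, which was apart. TIMP1 was at −1.26 and TIMP4 at 3.15, and the urokinase gene PLAU was at 1.01, with a probe at −0.58. TGFB2 was at −0.96, FGFR2 at −1.60 and PTH1R, the parathyroid hormone receptor gene, at −2.28, and these were 0.09, 1.02 and −0.58 against the control of L3/4. ACTA2 was at 0.23 and TPM1 at −2.73. To the control of L3/4 TIMP1 was at −0.25, PLAU at 0.75, ACTA2 at −0.40 and TPM1 at −0.64, all under 2-fold, while TIMP4 was not well above background there. The glycosaminoglycan synthesis list had a median of −0.84 at percentile 1.30, with 1 of 6 members at least 2-fold lower, TNFAIP6, a hyaluronan-binding protein, at −1.51, which had a probe of the opposite sign. This list stood apart under 5 of 11 alternatives only, with medians of −0.28 against the other control and −0.32 with normexp. The Schwann and neural list had a median of 1.27 at percentile 98.4, with 2 of 3 members at least 2-fold higher, S100B at 1.53 among them, and 1 at least 2-fold lower. It stood apart in that direction under 5 of 11 alternatives only, with a median of 0.29 with normexp, a mean of 0.54 in place of the median, and a median of −0.85 against the other control. Further genes with high ratios were TACC3 at 3.79, PRKCB at 3.52, PSAT1, an enzyme of serine synthesis, at 3.51, HGF, hepatocyte growth factor, at 3.40 and APOD, apolipoprotein D, at 3.19. Against the other control these were 1.77, 0.45, 2.46, 1.94 and 3.53 for TACC3, PRKCB, PSAT1, HGF and APOD.

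Of 13715 features well above background on both arrays, 1073 were at least 2-fold higher and 1255 at least 2-fold lower at the fused levels. Of those measured on the other control too, 612 of 965 higher features and 545 of 1133 lower ones were also 2-fold apart from that control in the same direction. The share of calls that were higher was 46.1%, and 62.1% with normexp.

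**Figure D2:**
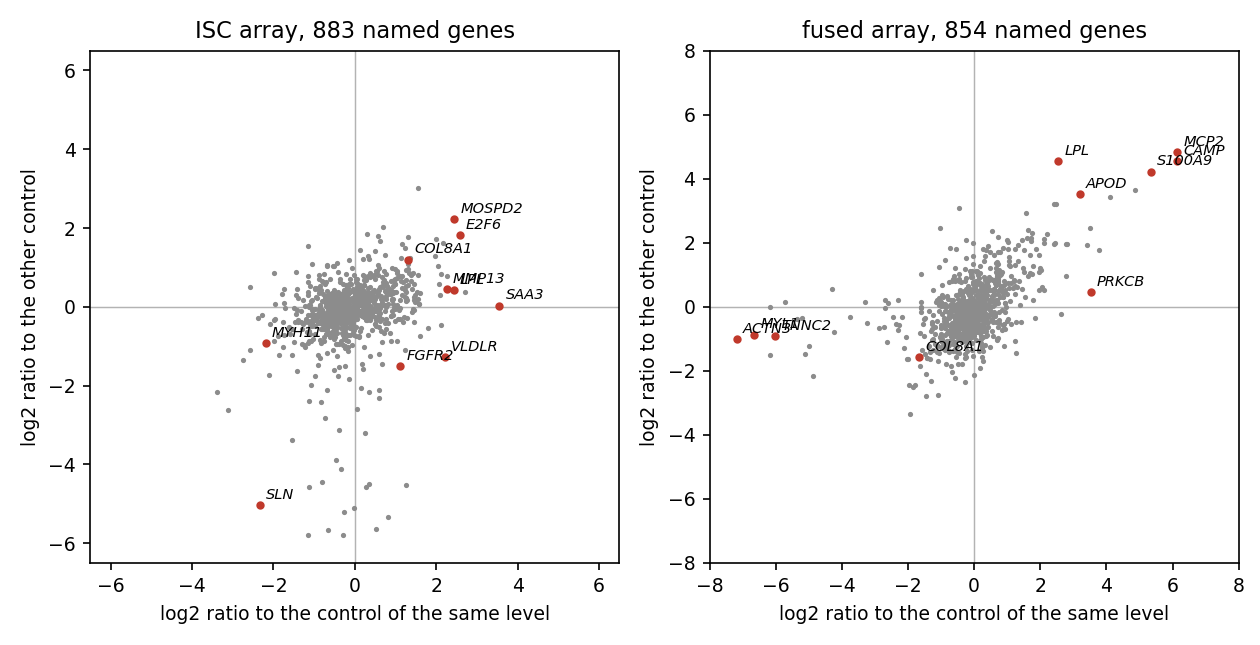
Log2 ratio of each named gene to the control of the same lumbar level (horizontal axis) and to the other control (vertical axis), for the ISC array (left, 883 genes) and the fused array (right, 854 genes), with 1 point per gene well above background on the 3 arrays used. For the fused array CAMP lies at 6.14 and 4.56, while for the ISC array SAA3 lies at 3.55 and 0.03.

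The control arrays of the different lumbar levels were compared as background. Skeletal muscle genes were lower in the control of L3/4, 11 of 13 by at least 2-fold, with TNNC2 at −5.09, MYL1 at −5.78 and CKM at −4.96. Glycolysis genes were lower as well, 6 of 9 by at least 2-fold, and the Schwann and neural list was higher, with a median of 1.23 at percentile 98.6. Of 13137 features, 1101 were at least 2-fold higher and 1207 at least 2-fold lower in the control of L3/4. These are 8.38% and 9.19% of features, beside 9.08% and 10.5% for the ISC level and 7.82% and 9.15% for the fused levels. The share of calls that were higher was 47.7%, and 33.5% with normexp. Across probes, Pearson's r was highest between the ISC level and the control of L2/3 and L4/5 at 0.954, and was 0.930 between the ISC level and the control of L3/4.

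**Figure D3:**
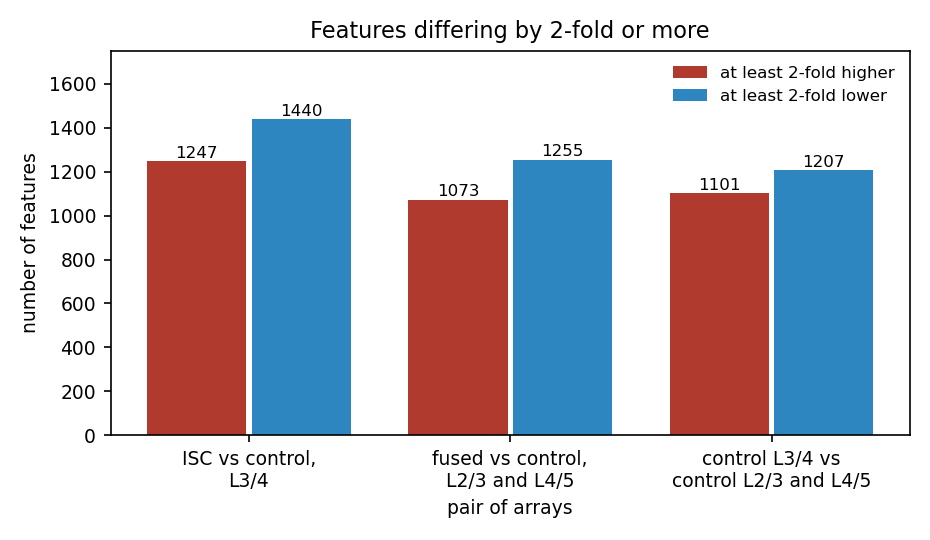
Number of features at least 2-fold higher (red) or lower (blue) in the first of a pair of arrays than in the second, for the ISC level (1247 and 1440), the fused levels (1073 and 1255) and the control of L3/4 against the control of L2/3 and L4/5 (1101 and 1207).

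The ratios at the stressed and at the fused levels share no array and were set against each other over 12742 features measured on all 4 arrays. COL8A1 was the gene of the matrix lists that was 2-fold higher at the ISC level and 2-fold lower at the fused levels against both controls. BGN and TIMP1 were higher at the ISC level and lower at the fused levels against the matched controls, and S100A9, TACC3 and PPARG lower at the ISC level and higher at the fused levels. Across genes, which are not independent replicates, Pearson's r was −0.008 and Spearman's rho 0.016. Features 2-fold higher in both numbered 118, where independent lists would share 91.9, and those lower in both numbered 162, where 102.8 would be shared. Features higher at the ISC level and lower at the fused levels numbered 167 against 107.8, and the reverse 139 against 87.6. All of these overlaps lie above those of independent lists, in the same and in opposite directions alike.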

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

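All tests in this part were chosen after the results were seen. The difference between the ISC ratio and the fused ratio was not tested for any gene, since each ratio rests on 1 array each way. The genes below were at least 2-fold apart from the matched control at both levels, in opposite directions.

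Matrix and lipid genes higher at the ISC level and lower at the fused levels were COL8A1, with a difference of the log2 ratios of 2.98, BGN with 3.34, TIMP1 with 2.31 and VLDLR with 3.23. FGFR2 differed by 2.71 and MYL1 by 7.90. Genes lower at the ISC level and higher at the fused levels were S100A9 with −6.47, PRKCB with −6.11, TACC3 with −5.75, PPARG with −4.63 and S100B with −2.60. Of these genes, COL8A1 alone kept both directions at 2-fold against the other control, at 1.20 for the ISC level and −1.58 for the fused levels. FGFR2, at −1.50 and 1.02, and VLDLR, at −1.27 and 2.45, were 2-fold apart there with both directions turned over.

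Skeletal muscle genes were far lower at the fused levels than in the control of the same levels. Muscle tissue in the control sample of L2/3 and L4/5 is a candidate explanation, since the control of L3/4 lay below it by a median of −4.85 with an SD of 2.23 over 12 genes. Whether that muscle came from dissection or belongs to those lumbar levels stays open. A loss with fusion cannot be told apart from this: the fused levels lay below the control of L3/4 by a median of −0.97 with an SD of 0.78, but that control is of another level and the controls differ, so it is no sure baseline.

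Granulocyte genes were higher at the fused levels than in either control. A low value in the control of L2/3 and L4/5 as the whole cause is argued against for CAMP, S100A9, MCP2 and BPI, whose median signal was −1.17 there, −0.04 in the control of L3/4, −0.85 at the ISC level and 4.29 at the fused levels, which lay above the highest of the other 3 arrays by a median of 4.39, SD 0.61. Whole blood like that in the other samples would keep the ratio of these 4 genes to the haemoglobin genes. Their log2 ratio to haemoglobin at the fused levels, −4.88, was 3.38 above the highest of the other 3 arrays. All 4 were among the genes with the highest ratios at the fused levels, however. Part of this excess thus follows from their choice, and it cannot decide on blood. For CXCR2 of the neutrophil list, which was not among those highest genes, blood stays open as well. Its ratio to haemoglobin, −8.38, lay within those of the other arrays, with a difference of −0.76 from the highest, and 1 gene does not decide. Marrow in the sample, local inflammation at the fused levels, the fusion surgery itself and a difference between lumbar levels that the control sample missed were not tested, and all stay open.

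The ISC ratios were mirrored by the ratio of the controls, with r = −0.717 across 12742 features, where −0.5 is expected for equally noisy arrays. The covariance of the ISC ratio with the ratio of the controls made up 73.2% of its variance. Sharing the control array of L3/4 gives part of this by construction, as it does for r, so only the excess speaks for that array being unusual. The same share for the fused ratio, which shares the control of L2/3 and L4/5, was 30.2%. Much of the variance of the ISC ratio may thus come from the control array of L3/4. Spot noise is argued against by the r of 0.771 between probes of 1 transcript. Mean brightness accounted for 2.23% of the variance, which argues against a brightness-dependent difference only among these features, well above background on all 4 arrays. Dimmer features were left out, so a difference in sensitivity stays open for them. In this comparison 2241 features were well above background at the ISC level only and 543 in the control of L3/4 only. Whether that control sample differs by animal, tissue or labelling stays open. So does an effect of stress or of the resection over L3/4, neither of which could be tested with 1 array per group.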

How the results depend on the processing

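The use of the other control and of normexp on median signals was chosen after seeing the data, and the remaining settings before. Normexp as first planned, on mean signals, was not run. No paired analysis was possible because each group holds 1 array and no test was made, and no array could be left out. Normexp gave 347 higher and 176 lower features for the ISC level, 437 and 267 for the fused levels and 140 and 278 for the controls, which changes signal column, background correction and offset together, and the cause was not tested. Counting features well above background on at least 1 array gave 2681 higher for the ISC level, 2111 higher and 1921 lower for the fused levels, and 1927 and 2289 for the controls, and the higher share for the ISC level was then 57.6%. A size of 1.5-fold gave 2472 and 3621, 2121 and 2937, and 2711 and 2409, and of 3-fold 388 and 412, 535 and 426, and 336 and 426, for the ISC level, the fused levels and the controls. The ISC counts were 530 and 563 against the mean of the controls and 499 and 710 against the other control, and the correlation of the ISC and fused ratios was then 0.129. The counts of named genes that follow cover those measured at 2-fold to the matched control, with LIF and IL1A left out. Among them, ratios of opposite sign against the other control were VLDLR −1.27, PRKCB 0.49, IGF1 0.67, FGFR2 −1.50, S100B 0.16, MYL1 −4.53, PPARG 0.86, TACC3 0.06 and KDR 1.06 for the ISC level, and PYGM 1.497, PPP1R3A 0.15, MYOZ1 3.097, FGFR2 1.02, ALDOA 0.14, GAPDH 0.21, PPARG −0.22 and VLDLR 2.45 for the fused levels, where IGF1, KDR, PYGM and MYOZ1 were not well above background in the control used. Some named genes under 2-fold turned sign as well. Of the named genes at 2-fold, 12 of 42 for the ISC level and 26 of 51 for the fused levels were still 2-fold apart in the same direction against the other control, and these include the genes named because they were apart from both controls. The Schwann and neural list was then 0.16 and −0.85. With normexp the named genes kept were 17 of 42 and 40 of 51. Against the mean of the controls, FGFR2 was −0.19 and MYL1 −1.64 for the ISC level, and VLDLR 0.72 and that list −0.086 for the fused levels. The cause was not tested beyond the distance between the controls. The smooth muscle list at the ISC level and the adipocyte, neutrophil and skeletal muscle lists at the fused levels stood apart in the same direction under all 11 alternatives run, the protease list at the ISC level and the glycolysis list at the fused levels under 10, the mitochondrial and the Schwann and neural lists at the ISC level under 9, and the glycosaminoglycan and the Schwann and neural lists at the fused levels under 5. The last 2 were lost with normexp, the filter on all 4 arrays, averaged probes, the list mean and either change of control, and the mitochondrial list with averaged probes and the other control. For the smooth muscle list these alternatives cannot decide whether its genes were lower. Either change of control brings in the control with high skeletal muscle signal, and the other alternatives keep the control of L3/4. Against the other control 2 of the 6 members were at least 2-fold lower, DES at −4.575 among them. There MYH11 was at −0.92, ACTA2 at −0.42 and CALD1 at 0.28. Signal over background limits the dim genes most, which have bounds only.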

Other observations

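The tests and genes in this part were chosen after the data were seen, except for the lists. Against both controls, 14 named genes were at least 2-fold higher and 16 at least 2-fold lower at the ISC level. The lower ones include ENO3 of the skeletal muscle list, at −1.14 to the matched control and −5.79 to the other. That other control held high signal of skeletal muscle genes, so for such genes being lower than it says little of the ISC level. Among the higher ones were the growth factor genes HGF, at 1.56 to the matched control and 3.01 to the other, and PDGFD, at 1.96 and 1.28. PTGS2 was at 1.31 and 1.78, with a probe of the opposite sign in the matched comparison. HGF and PTGS2 were higher at the fused levels as well, so that both were 2-fold higher in the ISC and the fused sample than in either control.

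At the fused levels, 48 named genes were 2-fold higher and 38 were 2-fold lower than both controls. The lower ones include genes of the skeletal muscle list, such as ENO3 at −6.16 to the matched control and −1.51 to the other, and ACTN3 at −7.18 and −1.01. Their matched control held high signal of skeletal muscle genes, so for these the matched ratio says little of the fused levels. Among the higher ones the adhesion molecule gene VCAM1 was at 2.21 to the matched control and 2.27 to the other, the interferon gene IFNG at 2.42 and 3.21, the haptoglobin gene HP at 1.71 and 2.16, and the neutrophil chemokine receptor gene CXCR2 at 1.32 and 1.44. Lower than both controls were MGP, the matrix Gla protein that inhibits calcification, at −1.33 and −1.43 with all 9 probes between −1.57 and −1.32 in the matched comparison, EMP1 at −1.44 and −1.61 and MYOC, myocilin, at −1.57 and −1.36. COL8A1 and LUM belong to the same set.

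Of the 12742 features measured on all 4 arrays, the fused array was at least 2-fold above the other 3 in 461 and below them in 308, and the control of L3/4 in 347 and 427. The ISC array was above the others in 56 and below them in 51, and the control of L2/3 and L4/5 in 165 and 91. The array of the stressed level was thus the one that stood apart from the rest least often.

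Some lists of interest for a ligament did not stand apart. The list of mechanosensing and cytoskeleton genes had a median of −0.57 at percentile 10.7 for the ISC level and −0.16 at percentile 39.6 for the fused levels. The sign for the ISC level was not stable, with a median of 0.28 when the probes of a gene were averaged and 0.24 against the other control. The osteoblast and bone list had medians of −0.31 and −0.81, at percentiles 45.3 and 10.7, and of 0.02 and −1.15 against the other control. The reference genes of common use had medians of 0.04 and 0.02.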
